A study of Mus musculus with 29 samples.

How the data were processed

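Messenger RNA was measured by RNA sequencing in the liver and the hippocampus of male C57BL/6J mice made obese by diet. Per the labels' protocols, RNA came from about 20 mg of tissue, polyadenylated transcripts were selected from 1 µg of total RNA, and strand-specific TruSeq libraries were sequenced as paired reads of 125 nt. All mice ate high-fat diet for 10 weeks and then spent 4 weeks on 1 of 4 regimens: continued high-fat diet (HFD), high-fat diet with fasting every other day (HFD-IF), control chow (CC), or control chow with intermittent fasting (CC-IF). The series design states 32 samples, and 29 libraries were analysed here. Liver had 4 HFD, 2 HFD-IF, 4 CC and 4 CC-IF libraries, and hippocampus had 4 HFD, 4 HFD-IF, 4 CC and 3 CC-IF libraries. The series design calls the samples of a group biological replicates, so p-values measure the spread between such samples.

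The authors deposited 1 table of FPKM (fragments scaled by transcript length and by the mapped fragments of the library) with 24346 rows of genes. Per the submitters' processing notes, the tools named were FastQC 0.11.9, Trimmomatic 0.39, TopHat2 2.1.1 and Bowtie2 2.3.5.1, with the mouse genome build GRCm38 (mm10). The program that computed FPKM, its annotation and any scaling between libraries are not given in the sources used here. Each column was tied to a tissue and regimen by its name, and 0 columns were left without a group. The columns count libraries from 0 and the labels count samples from 1, so a column was assigned to its group and not to a numbered sample. Libraries are named below by the index in their column.

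FPKM carries no direct depth. Low values were read as whole numbers of fragments to estimate it, a method chosen after looking at the values. The estimates were 9.45 to 15.7 M (mega) fragments for liver and 11.1 to 37 M for hippocampus. They are approximate, because 61.6% to 74.4% of the low values in liver libraries and 56% to 70.7% in hippocampal libraries lay within 0.2 of a whole fragment, where chance gives 40%. Genes whose longest transcript is under 300 nt, mostly small nucleolar RNAs, took 97.1% to 99.9% of the summed FPKM of a library, and their FPKM cannot be read as abundance. Over 40 pairs of libraries of the same group, at least 99.99% of values differed and Pearson's r lay between 0.953 and 0.984, so no library was treated as a repeat of another.

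Tests were run with limma 3.58.1 in R 4.3.3, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and plots. Values were taken as log2(FPKM + 1), and genes were kept when their mean FPKM over the libraries of the tissue was at least 1, which left 11497 genes in liver and 12857 in hippocampus. Fold changes are on this log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The 4 regimens of a tissue entered 1 linear model with group as the only term, moderated with an intensity trend, and two-sided p-values were adjusted by the method of Benjamini and Hochberg at a threshold of 0.05. The contrasts were CC against HFD, HFD-IF against HFD, CC-IF against CC, CC-IF against HFD-IF, CC-IF against HFD, and the interaction, which is the fasting change on chow minus the fasting change on high-fat diet. A model over both tissues, on the 9939 genes kept in each and with all libraries treated as independent, tested whether a change differed between them. Errors after ± are standard errors for log2 changes and standard deviations for FPKM.

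A set of 56 gene lists was written before the data were examined, as were the groups, the tests, most alternatives and the rule for naming genes; 37 lists applied to liver and 42 to hippocampus. They cover pathways of energy, lipid, amino acid and succinate metabolism, stress responses, the circadian clock, and markers of the cell types that either dissection could hold. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a tissue. It was tested again with an estimated correlation and with fry, and the results of fry are not reported here. Lists with under 3 measured members were not tested. Where a gene is named for its size of change, it is among the 6 highest or 6 lowest log2 changes past the threshold in a contrast whose groups do not overlap, with predicted genes and near-identical families left out. The others named are up to 4 members with the smallest p of each list that passed or had at least 3 members past the threshold, members of the succinate list past the threshold with Sucnr1 and Sdha to Sdhd in any case, the 3 genes with the smallest p where none passed, and 6 genes for the interaction. Some genes that the rule names are not reported here. Coordinates are those of GENCODE M21 on GRCm38, matched by symbol.

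The procedure was tested on simulated data with 50 genes changed at each of several sizes. With 11497 liver genes it recovered 76% to 88% of changes of 1 on the log2 scale and 18% to 48% of changes of 0.5, depending on the contrast. With 12857 hippocampal genes it recovered 90% to 98% and 54% to 70%. False calls were 7 of 181 to 18 of 198 in a contrast, and real rates may differ. Alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling between libraries, a fit on only the groups compared and each library left out in turn. Added after the data had been seen were leaving out genes under 300 nt, removing trends on transcript length and GC content (known for 99.3% of genes in each tissue), a term for a split between hippocampal libraries, a fit on 9 hippocampal libraries, the column index as a block, and leaving HFD-IF library 1 out of the shared spread in liver. Median-ratio scaling shifted the median of all genes by at most 0.0591 in size in any contrast.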

Results

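The data describe liver and hippocampus of obese mice after a diet switch, intermittent fasting, or both, in 29 libraries of 8 groups. The title of the study names succinate, an intermediate of the citric acid cycle that also acts on the receptor Sucnr1, so genes of succinate metabolism are reported for every contrast. Liver libraries held 15087 to 16343 genes above 0 and hippocampal libraries 17160 to 18057, at estimated depths of 9.45 to 15.7 M (mega) and 11.1 to 37 M fragments. In liver, genes passed the threshold in every contrast, and in hippocampus 1 gene passed in all contrasts together.

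The switch from high-fat diet to chow without fasting addresses what diet alone changed. In liver, 7 of 23 genes of the urea cycle and amino acid breakdown, 5 of 38 of fatty acid oxidation and 1 of 25 of cholesterol synthesis fell on chow. These lists were lower as sets in limma's camera at the preset correlation, and had adjusted p = 0.234, 0.669 and 0.669 with an estimated correlation. Cfd, which encodes the adipocyte-secreted complement factor D, ranged from 5.29 to 70.9 FPKM in the 4 HFD livers and was at most 0.205 FPKM in the 4 CC livers (chromosome 10, 79890853 to 79892655). It was the only one called of 3 measured adipocyte genes, which did not pass as a set (limma's camera, adjusted p = 0.106). Bhmt, a methionine-forming enzyme, fell from 2356 ± 538 to 557 ± 97.9 FPKM, while Fabp5, a fatty acid carrier, rose from 11.4 ± 3.9 to 70.0 ± 34.8 FPKM and Lepr, the leptin receptor, from 1.06 ± 0.396 to 6.59 ± 2.76 FPKM (SD, n = 4 and 4). In limma, 39 genes rose and 226 fell of 11497, and 2148 had an unadjusted p under 0.05.

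Of 23 measured genes of the urea cycle and amino acid catabolism, 0 rose, 7 fell and 16 did not pass, and 15 were lower when adjusted over the list alone. Prodh, which begins proline breakdown, fell by 0.80 on the log2 scale, Asl of the urea cycle by 0.62, Arg1 (arginase) by 0.48 and Hpd of tyrosine breakdown by 0.55. The list was lower than other genes in limma's camera (adjusted p = 1.8e-09, median -0.41, 21 of 23 members lower), with adjusted p = 0.234 with an estimated correlation. Among 38 targets of PPAR alpha and genes of fatty acid oxidation, 0 rose and 5 fell, or 1 and 13 adjusted over the list alone, among them Hadh (-0.71 ± 0.13) and Acaa1a (-0.70 ± 0.13) of beta oxidation (camera adjusted p = 9.55e-06 in limma, adjusted p = 0.669 with an estimated correlation). All 25 genes of cholesterol synthesis and uptake were lower, 1 of them (Hmgcs1, -1.16 ± 0.26) past the threshold and 10 adjusted over the list alone. Adjusted p was 4.12e-07 in limma's camera, and adjusted p = 0.669 with an estimated correlation. Mogat1, a triglyceride synthesis enzyme, fell by 1.45 as the only called member of the 18 lipid droplet genes, of which 6 were lower adjusted over the list alone. Adjusted p was 0.0068 in limma's camera, and adjusted p = 0.653 with an estimated correlation. In xenobiotic metabolism 2 of 27 genes fell, 4 adjusted over the list alone, and Cyp2a5 fell by 1.73. Adjusted p was 0.0369 in limma's camera, and adjusted p = 0.669 with an estimated correlation. Gpt, which makes pyruvate from alanine, fell by 0.77 as 1 of 14 gluconeogenic genes, 4 adjusted over the list alone, with the same camera p as for xenobiotic genes and adjusted p = 0.669 with an estimated correlation.

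All 45 cytosolic ribosomal protein genes were higher on chow, with a median of 0.22, although 1 passed the threshold, and 10 did adjusted over the list alone. Adjusted p was 2.39e-16 in limma's camera, and adjusted p = 0.653 with an estimated correlation. The citric acid cycle (1 of 25 fell, 7 adjusted over the list alone) and oxidative phosphorylation (0 of 70, and 0 adjusted over the list alone) were lower as sets, and the unfolded protein response (0 of 20) and male-biased liver genes (0 of 19) were higher, with 0 adjusted over the list alone in each. Their limma camera adjusted p-values were 0.000303, 0.0111, 0.0027 and 0.0161, and with an estimated correlation adjusted p = 0.669, 0.748, 0.669 and 0.697. Without some library 6 of the 12 lists lost their camera call. The male-biased median of 0.559 was 0.228 without HFD library 3 (adjusted p = 0.225), the gluconeogenic one of -0.334 was -0.215 without CC library 3 (0.0841), and the xenobiotic one of -0.15 was -0.26 without HFD library 0 (0.0596). Other genes named for their size were Btg3, Adgrf1, Cdc42ep5 and the short Vaultrc5, which rose by 1.97, 1.95, 1.81 and 1.55, and Sema5b, Acss3 and Clstn3, which fell by 1.74, 1.70 and 1.65 on the log2 scale. The 4 CC and 4 HFD livers did not overlap in 14.1% of all 11497 genes, where chance separates 2.86%. The count of 265 fell to 89, 101 and 51 without HFD libraries 3, 2 and 0 and to 69, 98 and 102 without CC libraries 0, 2 and 1, and 17 of the 24 named genes past the threshold lost their call without some library. It was 497 in a fit on these groups alone and 512, with all 265 shared, with HFD-IF library 1 left out of the shared spread.

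Fasting on continued high-fat diet addresses whether fasting acts without a change of diet. In liver, 21 of 25 genes of cholesterol synthesis and uptake and 7 of 20 of fatty acid synthesis fell (limma's camera, adjusted p = 0.319 with an estimated correlation for each list). Sqle, squalene epoxidase (chromosome 15, 59315077 to 59331192), fell from 30.9 ± 10.4 FPKM in 4 HFD livers to 1.54 ± 0.896 FPKM in 2 HFD-IF livers, and Fasn, fatty acid synthase, from 235 ± 110 to 22.2 ± 4.58 FPKM. Igfbp2, an insulin-like growth factor binding protein, rose from 183 ± 18.5 to 710 ± 483 FPKM, and Myc, a growth-related transcription factor, from 2.03 ± 0.967 to 11.9 ± 1.18 FPKM. limma called 41 genes higher and 111 lower, with 2043 at an unadjusted p under 0.05.

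Of 25 genes of cholesterol synthesis and uptake, 21 fell and 0 rose, 24 adjusted over the list alone, with a median of -1.82. Adjusted p was 1.04e-30 in limma's camera, and adjusted p = 0.319 with an estimated correlation. Fdps and Idi1 of the isoprenoid steps fell by 3.62 and 3.48, and Nsdhl by 2.73 on the log2 scale, as did Dhcr7 of the last sterol step (-2.64 ± 0.36). In fatty acid synthesis 7 of 20 fell, 13 adjusted over the list alone, including Thrsp, a lipogenic regulator (-4.14 ± 0.76), and Acacb, which makes malonyl-CoA at mitochondria (-2.28 ± 0.44). The camera adjusted p in limma was 9.88e-11, with adjusted p = 0.319 with an estimated correlation. The chaperones Calr, Pdia6 and Pdia3 of the endoplasmic reticulum fell by 1.34, 1.30 and 0.99 as 3 of 20 genes of the unfolded protein response, of which 15 were lower and 1 higher adjusted over the list alone. Adjusted p was 1.99e-08 in limma's camera, and adjusted p = 0.547 with an estimated correlation. PPAR alpha targets were higher as a set (33 of 38 members), with 0 past the threshold and 16 adjusted over the list alone. Hadhb had a log2 change of 0.66 ± 0.15 and Acot2 of 2.45 ± 0.61 (limma, adjusted p = 0.056 and 0.0721; camera adjusted p = 1.11e-09, and adjusted p = 0.547 with an estimated correlation). Oxidative phosphorylation (67 of 70 members), the urea cycle and amino acid list (19 of 23) and liver endothelium (11 of 13) were lower as sets, with 0, 1 and 0 members called and 0, 6 and 0 adjusted over the list alone. Adjusted p was 1.11e-09, 0.000269 and 0.00958 in limma's camera, and adjusted p = 0.547 with an estimated correlation in each.

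Markers of other cells were higher in the HFD-IF livers, with 0 members past the threshold in each list. The median was 1.15 over 10 genes of infiltrating and lipid-associated macrophages, 0.732 over 6 MHC class II genes, 0.632 over 24 genes of fibroblasts and extracellular matrix and 0.615 over 19 interferon response genes. Adjusted p was 0.000615, 0.0138, 5.36e-08 and 8.89e-05 in limma's camera, and adjusted p = 0.547 with an estimated correlation in each. Of these, 4 matrix genes were higher adjusted over the list alone, and 0 genes of the other lists. These medians depended on HFD-IF library 1, which also held the most genes above 0 (16343), and without it they were 0.0441, -0.3, -0.00973 and -0.0951. Oxidative phosphorylation had a median of -0.0611 against -0.219 without it (camera adjusted p = 0.117), and endothelium of -0.17 against -0.284 without HFD-IF library 0 (0.103). Tuba8, Uap1l1 and Usp2 rose by 2.06, 1.99 and 1.79, and Btg3 also rose. Snora30, a small nucleolar RNA under 300 nt, was listed at 0 in both HFD-IF livers. The 2 HFD-IF and 4 HFD livers did not overlap in 22.2% of all genes, where chance separates 13.3%. All 18 named genes past the threshold lost their call without some library, where leaving out an HFD-IF library leaves 1 that is assumed to vary like the other groups. Without HFD-IF library 1 the log2 changes of Sqle, Dhcr7 and Fasn were -3.27, -2.85 and -3.04 (limma adjusted p = 0.0556, 0.0563 and 0.167), and those of Tuba8, Uap1l1 and Igfbp2 were 1.25, 1.13 and 1.01 against 2.06, 1.99 and 1.77 (0.147, 0.322 and 0.146). Without HFD-IF library 0, Acot2 and Hadhb passed at 3.54 and 0.71 (limma adjusted p = 0.00442 and 0.037). The count was 53, 61, 81 and 92 without HFD libraries 3, 2, 0 and 1, 1633 without HFD-IF library 0 (805 higher and 828 lower), 5 without HFD-IF library 1, and 8 in a fit on these groups alone.

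**Figure D1:**
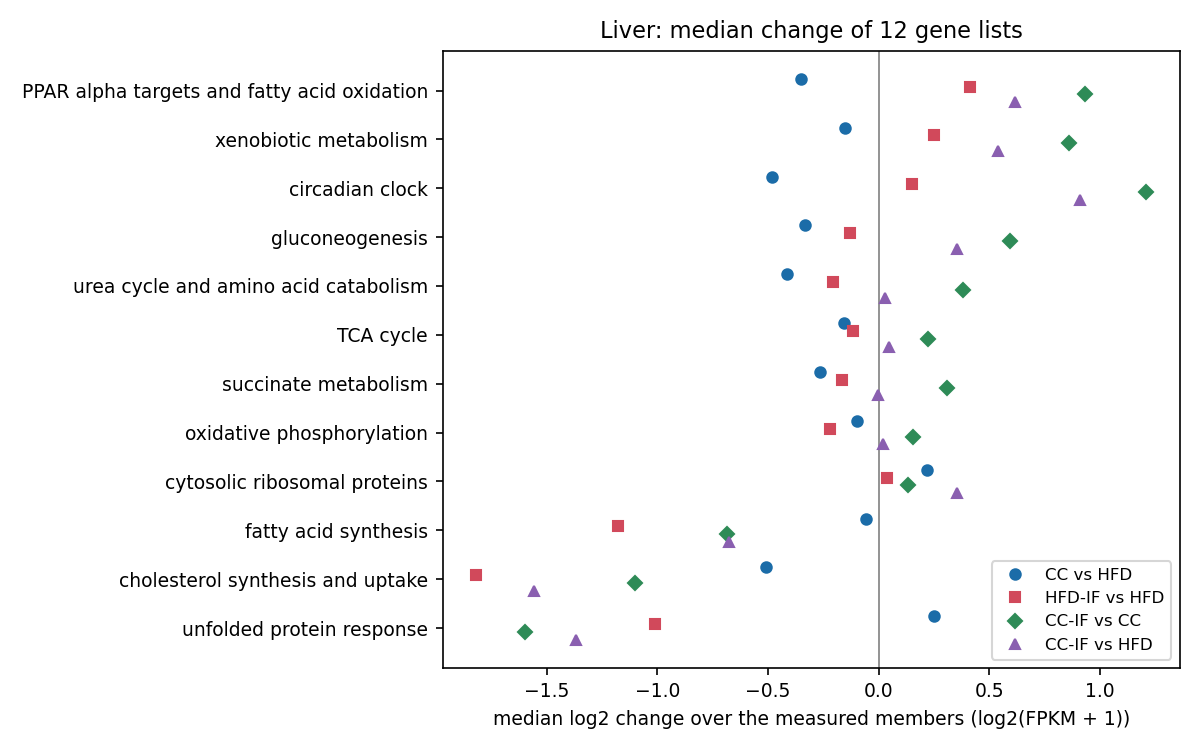
Median log2 change on the log2(FPKM + 1) scale (horizontal axis) over the measured members of 12 gene lists in liver, with a symbol for each of 4 contrasts. With fasting on chow, PPAR alpha targets had a median of 0.935 and the unfolded protein response a median of -1.6.

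Fasting on chow raised 32 of 38 PPAR alpha targets and oxidation genes, 15 of 27 of xenobiotic metabolism and 11 of 18 clock genes in liver, and lowered 17 of 20 of the unfolded protein response, 18 of 25 of cholesterol synthesis and 8 of 20 of fatty acid synthesis. In limma's camera these lists had adjusted p = 0.335, 0.247, 0.247, 0.247, 0.441 and 0.476 with an estimated correlation. Acot3, a peroxisomal acyl-CoA thioesterase (chromosome 12, 84052144 to 84060402), rose from 2.59 ± 2.91 to 125 ± 45.4 FPKM, and Cyp4a14, a fatty acid hydroxylase controlled by PPAR alpha (chromosome 4, 115486200 to 115496142), from 168 ± 195 to 2618 ± 569 FPKM (SD, n = 4 and 4). Usp2, a clock-controlled deubiquitinase (chromosome 9, 44067021 to 44095627), rose from 1.79 ± 0.449 to 54.9 ± 5.34 FPKM. Pdia6, a folding enzyme (chromosome 12, 17266545 to 17284770), fell from 180 ± 28.1 to 39.2 ± 8.81 FPKM. limma called 1633 genes higher and 1123 lower, of which 233 and 198 changed by at least 2-fold, and 4195 had an unadjusted p under 0.05.

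Of 38 PPAR alpha targets and oxidation genes, 32 rose and 1 fell (32 and 2 adjusted over the list alone), including Acaa1a (1.44 ± 0.13), Acot4 (2.76 ± 0.31) and Cyp4a10 (4.75 ± 0.74). Reads of the Cyp4a and Acot families may be shared between close copies. The limma camera adjusted p was 2.09e-14, with adjusted p = 0.335 with an estimated correlation. In the unfolded protein response 17 of 20 fell and 0 rose, also adjusted over the list alone, with Calr at -2.05, Sdf2l1 at -3.96 and Manf at -2.68. Adjusted p was 1.19e-13 in limma's camera, and adjusted p = 0.247 with an estimated correlation. Cholesterol genes fell in 18 of 25 and rose in 1 (19 and 1 adjusted over the list alone), with Sqle at -3.08 and Cyp51 at -2.40, and fatty acid synthesis genes fell in 8 of 20 and rose in 1 (11 and 1 adjusted over the list alone), with Fasn at -2.72 and Acacb at -2.32. Camera in limma gave adjusted p = 1.78e-09 and 0.000602, and adjusted p = 0.441 and 0.476 with an estimated correlation. Xenobiotic metabolism rose in 15 of 27 and fell in 1, the same numbers as adjusted over the list alone, led by Cyp2a5 (3.69 ± 0.27) and Por, the electron donor of cytochromes P450 (3.15 ± 0.26). Adjusted p was 1.38e-05 in limma's camera, and adjusted p = 0.247 with an estimated correlation. Gluconeogenesis rose in 8 of 14, 10 adjusted over the list alone, with Gpt at 1.05 and Pcx, pyruvate carboxylase, at 0.86. Adjusted p was 0.000111 in limma's camera, and adjusted p = 0.247 with an estimated correlation.

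The circadian clock list rose in 11 of 18 genes and fell in 3, or 12 and 3 adjusted over the list alone. Ciart, Per3 and Per2 of the negative limb rose by 3.18, 3.36 and 2.44, and Dbp, an output transcription factor, by 4.18 ± 0.86. Adjusted p was 0.000276 in limma's camera, and adjusted p = 0.247 with an estimated correlation. In the urea cycle and amino acid list 14 of 23 rose and 2 fell, the same numbers as adjusted over the list alone. Asl rose by 1.45 and Hpd by 0.87, while Kynu of tryptophan breakdown and Cbs of transsulfuration fell by 0.82 and 1.06. Adjusted p was 0.000602 in limma's camera, and adjusted p = 0.34 with an estimated correlation. Sex-biased genes moved apart. Of 7 female-biased genes 6 rose, also adjusted over the list alone, with Fmo2 at 2.13, Cux2 at 2.37 and Cyp2b9 at 5.68, and of 19 male-biased genes 6 fell, 10 adjusted over the list alone, with Elovl3 at -3.87, Serpina1e at -5.57 and Selenbp2 at -4.11. The limma camera adjusted p-values were 0.000797 and 0.000645, and adjusted p = 0.34 and 0.562 with an estimated correlation. Cyp2b9, Serpina1e and Selenbp2 belong to families of close copies.

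Mitochondrial biogenesis genes rose in 6 of 16 and fell in 1, or 7 and 1 adjusted over the list alone, with Esrra, a nuclear receptor of mitochondrial genes, at 1.09 ± 0.08 and Mfn2 at 0.65 ± 0.09. Adjusted p was 0.0065 in limma's camera, and adjusted p = 0.247 with an estimated correlation. Citric acid cycle genes rose in 11 of 25 and fell in 2 (12 and 2 adjusted over the list alone), oxidative phosphorylation rose in 8 of 70 (3) and cytosolic ribosomal proteins in 4 of 45 (1). Their camera adjusted p-values in limma were 0.00154, 0.00719 and 0.0144, and adjusted p = 0.513, 0.706 and 0.706 with an estimated correlation. The ATF4 amino acid response fell in 5 of 16 genes, 6 adjusted over the list alone, among them Atf4 itself (-0.56 ± 0.14) and Fgf21, a fasting-related hormone (-1.91 ± 0.52). Adjusted p was 0.0368 in limma's camera, and adjusted p = 0.455 with an estimated correlation. Fgf21 lost its call without CC library 1 (limma adjusted p = 0.054, log2 change -1.76) and without CC-IF library 1 (0.0537, -1.72). Interferon response genes fell in 2 of 19, Kupffer cell markers in 2 of 14 and liver endothelium in 1 of 13, or 1, 0 and 1 adjusted over the list alone. Adjusted p was 0.00352, 0.0144 and 0.0449 in limma's camera, and adjusted p = 0.565, 0.562 and 0.562 with an estimated correlation. The ATF4, oxidative phosphorylation, ribosomal protein and endothelium lists lost their camera call without some library (adjusted p from 0.0506 to 0.193).

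Several lists had called members without passing as a set. Glucocorticoid response genes rose in 7 of 17, also adjusted over the list alone, with Mt1 at 2.93 and Fkbp5 at 1.54, and lipid droplet genes rose in 6 of 18 and fell in 1 (8 and 2 adjusted over the list alone), with Pnpla2, the triglyceride lipase, at 1.06 and Cd36 at 1.72. Bile acid genes rose in 5 of 18 and fell in 2 (7 and 4 adjusted over the list alone), with Akr1d1 at 1.47 and the export pump Abcb11 at -1.05. Ketone body genes rose in 4 of 9 and fell in 2, the same numbers as adjusted over the list alone, with the monocarboxylate transporters Slc16a7 at 1.92 and Slc16a6 at -1.39. Autophagy genes (4 of 19 rose, 4 fell, Bnip3 at 1.51) and acute phase genes (3 of 24 rose, 4 fell, Serpina3n at 0.69, Hamp at -1.35) went both ways, as did NRF2 targets (4 and 1 of 17) and glycolysis (2 and 2 of 22, Slc2a1 at 0.85). Adjusted over the list alone these were 6 and 4, 3 and 4, 4 and 2, and 2 and 2. Snora65 fell by 4.14, and Snora30, Snora47 and Snora75 were listed at 0 in 3 of 4 CC-IF livers and at 464000, 148000 and 89300 FPKM in the remaining one. The groups did not overlap in 28.8% of all genes, where chance separates 2.86%. The count stayed between 1968 and 2669 without any 1 library, and of the 62 named genes past the threshold only Fgf21 and Snora75 lost their call. Snora75 did so without any library of these groups except CC-IF library 2, with adjusted p in limma from 0.0596 to 0.1.

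**Figure D2:**
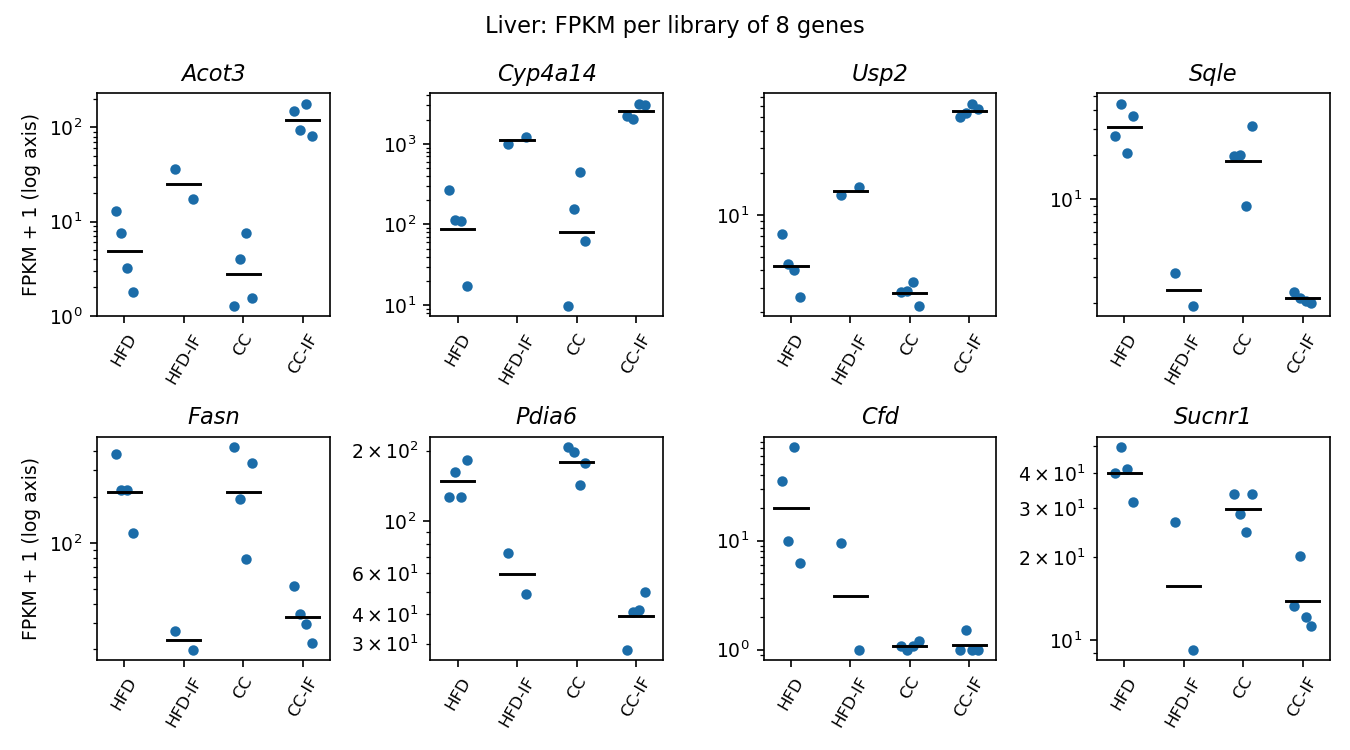
FPKM + 1 per liver library (vertical log axis, a point per library) for 8 genes in the 4 regimens, with a bar at the mean of log2(FPKM + 1) turned back to this scale. Usp2 averaged 54.9 FPKM in CC-IF and 1.79 FPKM in CC, and Sqle averaged 1.15 FPKM in CC-IF and 30.9 FPKM in HFD.

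Between the fasted groups, chow against high-fat diet shows what diet added under fasting. On chow 2 of 14 gluconeogenic, 2 of 18 clock and 2 of 23 urea cycle and amino acid genes rose and 1 of 19 interferon response genes fell. In limma's camera these lists had adjusted p = 0.292, 0.379, 0.425 and 0.425 with an estimated correlation, and 0 markers of Kupffer cells, macrophages, MHC class II or matrix passed. Usp2 rose from 13.8 ± 1.37 to 54.9 ± 5.34 FPKM and Asl from 286.5 ± 28.5 to 512 ± 68.4 FPKM, whereas Fos, an immediate early gene, fell from 3.08 ± 0.92 to 0.4 ± 0.255 FPKM and Ifit1, an interferon-induced gene, from 7.97 ± 4.25 to 2.02 ± 0.572 FPKM (SD, n = 2 and 4). limma called 45 genes higher and 23 lower, with 2091 at an unadjusted p under 0.05.

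Gluconeogenesis rose in 2 of 14 (Slc37a4, the glucose-6-phosphate transporter, 0.97; Foxo1, 0.91), the clock in 2 of 18 (Usp2, 1.91; Ciart, 1.68), the urea cycle list in 2 of 23 (Asl, 0.83; Arg1, 0.57) and mitochondrial biogenesis in 1 of 16 (Esrra, 0.51). Adjusted over the list alone 5, 7, 7 and 4 were higher, and 2 urea cycle genes lower. Adjusted p was 3.29e-05, 0.000592, 0.0018 and 0.00566 in limma's camera, and adjusted p = 0.292, 0.379, 0.425 and 0.292 with an estimated correlation. All 45 ribosomal protein genes and all 70 oxidative phosphorylation genes were higher, with 0 past the threshold and 28 and 0 adjusted over the list alone. Adjusted p was 1.29e-15 and 3.97e-12 in limma's camera, and adjusted p = 0.425 and 0.468 with an estimated correlation. Xenobiotic, citric acid cycle, fatty acid synthesis, glucocorticoid and succinate genes were also higher as sets, with 0 called and 10, 3, 4, 5 and 2 higher and 1 xenobiotic gene lower adjusted over the list alone. Adjusted p was 0.00225, 0.000333, 0.0114, 0.013 and 0.0173 in limma's camera, and adjusted p from 0.425 to 0.517 with an estimated correlation. Interferon response genes were lower in 18 of 19, 1 called and 12 adjusted over the list alone. Adjusted p was 5.08e-09 in limma's camera, and adjusted p = 0.425 with an estimated correlation. Lower as sets with 0 called members were matrix, Kupffer, macrophage, MHC class II, cell cycle, unfolded protein and ATF4 genes, with 0, 0, 0, 0, 0, 2 and 5 lower and 1 unfolded protein gene higher adjusted over the list alone. Their limma camera adjusted p-values ran from 1.65e-06 to 0.0114, and with an estimated correlation from adjusted p = 0.379 to 0.517.

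The matrix, Kupffer, macrophage and MHC class II medians of -0.56, -0.694, -1.01 and -0.892 turned to 0.14, 0.125, 0.753 and 0.242 without HFD-IF library 1, and the interferon median of -0.788 was -0.133 (limma's camera, adjusted p = 0.186). Without it those of succinate, fatty acid synthesis, ATF4 and cell cycle genes were 0.0439, 0.246, -0.0694 and -0.0109 against 0.208, 0.454, -0.574 and -0.392 (0.447, 0.0588, 0.257 and 0.911). Without HFD-IF library 0 those of glucocorticoid, unfolded protein and mitochondrial biogenesis genes were 0.218, -0.158 and 0.316 against 0.481, -0.551 and 0.203 (0.91, 0.257 and 0.0525). Succinate was at 0.154 without CC-IF library 1 (0.143) and macrophages at -0.639 without CC-IF library 2 (0.051). St3gal5, Map2k6, Ppp1r1b and Ppp1r3b rose by 1.63, 1.58, 1.51 and 1.32, and Irf5, Fam25c, Gbp6 and Pilra fell by 1.32, 1.28, 1.23 and 1.08. The groups did not overlap in 21.2% of all genes, where chance separates 13.3%. All 17 named genes past the threshold lost their call without some library, where leaving out an HFD-IF library again leaves 1 that is assumed to vary like the other groups. Without HFD-IF library 1 the log2 changes of Usp2 and Asl were 2.01 and 0.93 (limma adjusted p = 0.0869 and 0.0888) and that of Ifit1 was -1.0 against -1.50 (0.194). Without HFD-IF library 0 that of Ppp1r3b was 0.83 (0.0503). The count was 1773 without HFD-IF library 0 (933 higher and 840 lower), 5 without HFD-IF library 1, 1 without CC-IF library 0, 1 or 3, 5 without CC-IF library 2, 3 in a fit on these groups alone and 30 with no filter on low values.

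Chow with fasting against continued high-fat diet joins both interventions. In limma 1423 genes rose and 1303 fell, with 4236 at an unadjusted p under 0.05. Cholesterol genes fell in 22 of 25 (23 adjusted over the list alone; Sqle -3.83 ± 0.33, Dhcr7 -2.80 ± 0.29), and unfolded protein genes in 16 of 20 (16, with 1 higher; Calr -1.91 ± 0.19, Pdia6 -1.91 ± 0.19). Adjusted p was 1.61e-16 and 1.15e-09 in limma's camera, and adjusted p = 0.433 with an estimated correlation in each. Ribosomal protein genes rose in 34 of 45 (39 adjusted over the list alone; Rps9 0.51 ± 0.08), with a camera adjusted p of 7.09e-14 in limma and adjusted p = 0.448 with an estimated correlation. PPAR alpha targets rose in 24 of 38 and fell in 1 (26 and 1 adjusted over the list alone), led by Cyp4a14 (4.88), Acot3 (4.62), Cyp4a10 (3.78) and Cyp4a31 (3.49), the clock in 10 and 2 of 18 (11 and 2; Usp2 3.70), and xenobiotic genes in 11 and 1 of 27 (12 and 1; Por 2.84). Camera in limma gave adjusted p = 2.19e-09, 0.000492 and 0.000537, and adjusted p = 0.484, 0.433 and 0.433 with an estimated correlation.

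Fatty acid synthesis fell in 8 of 20 and rose in 1 (10 and 2 adjusted over the list alone; Fasn -2.72), while gluconeogenesis rose in 5 of 14 (6), glucocorticoid response in 5 of 17 (6) and female-biased genes in 3 of 7 (4; Cyp2a4 3.56, a close copy of Cyp2a5). The camera adjusted p-values in limma were 0.00134, 0.0068, 0.0068 and 0.0185, and adjusted p = 0.489, 0.433, 0.489 and 0.489 with an estimated correlation. Cfd was listed at 0 in 3 CC-IF livers and at 0.521 FPKM in the other, and its log2 change was -4.16 ± 0.73 (limma adjusted p = 0.00176). Serpina1e and Selenbp2 fell by 4.72 and 3.68, the short Snora34 by 3.68, and Snora47 was listed at 0 in 3 CC-IF livers. The groups did not overlap in 27.8% of all genes, where chance separates 2.86%. The count lay between 2027 and 2363 without any 1 library.

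Whether the fasting change depended on diet was tested as the interaction in liver. limma called 115 genes with a more positive fasting change on chow and 13 with a more negative one, with 2101 at an unadjusted p under 0.05. Asl went from 186 ± 21.0 to 512 ± 68.4 FPKM with fasting on chow, and was 286 ± 27.2 without and 286.5 ± 28.5 FPKM with fasting on high-fat diet. Cyp2a5 went from 59.3 ± 21.4 to 761 ± 190 FPKM on chow and was 194 ± 45.3 and 276.5 ± 7.80 FPKM on high-fat diet, and Gpt went from 104 ± 7.30 to 217 ± 27.1 and was 177 ± 12.7 and 167.5 ± 10.7 FPKM. Asl, Cyp2a5 and Gpt had interactions of 1.45 ± 0.19, 3.15 ± 0.42 and 1.13 ± 0.15, and Abhd15, Rhobtb1 and Arg1 of 1.43, 1.01 and 1.05 (limma adjusted p = 0.0116 for each of the 6), and all 6 kept their call without any 1 library. The urea cycle and amino acid list had 4 of 23 called, xenobiotic metabolism 4 of 27, the clock 2 of 18 and mitochondrial biogenesis 2 of 16, all positive. Adjusted over the list alone these were 15 positive and 1 negative, 11 and 1, 9 and 1, and 4 and 0. Adjusted p was 2.46e-09, 0.000317, 0.00025 and 0.00425 in limma's camera, and adjusted p = 0.151, 0.255, 0.241 and 0.156 with an estimated correlation.

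Gluconeogenesis and succinate metabolism had 1 positive call each, PPAR alpha targets and the ATF4 response 1 negative call each, and oxidative phosphorylation, the citric acid cycle and cholesterol genes 0. Adjusted over the list alone there were 6 and 0, 10 and 0, 12 and 1, 1 and 4, 0 and 0, 11 and 0, and 2 and 0 positive and negative genes. Camera in limma was positive for all of these but ATF4, which was negative, with adjusted p from 1.85e-12 to 0.00107, and adjusted p from 0.151 to 0.484 with an estimated correlation. Interferon, unfolded protein, matrix, Kupffer, MHC class II, macrophage and male-biased lists were negative and the female-biased list positive in camera (limma, adjusted p from 3.93e-09 to 0.03, and adjusted p from 0.31 to 0.614 with an estimated correlation), with 0 called. In these lists 4 interferon genes were negative and 2 female-biased genes positive adjusted over the list alone. Without HFD-IF library 1 the macrophage, Kupffer, matrix, MHC class II, ATF4 and cholesterol medians of -1.09, -0.866, -0.681, -1.19, -0.717 and 0.814 were 0.639, 0.00591, 0.0278, -0.0141, -0.249 and 0.356 (camera adjusted p from 0.0535 to 0.823). The male-biased median of -0.665 was 0.435 without HFD-IF library 0, -0.342 without HFD library 3 and -0.194 without CC-IF library 0 (0.962, 0.124 and 0.165), and the female-biased one of 1.52 was -0.083 without HFD-IF library 0 and 0.982 without CC-IF library 3 (0.896 and 0.0537). The count of 128 was 49, 48 and 65 without HFD libraries 3, 2 and 0, 1766 and 28 without HFD-IF libraries 0 and 1, 45, 36 and 34 without CC libraries 0, 2 and 1, and 49, 16, 26 and 208 without CC-IF libraries 0, 1, 3 and 2; with median-ratio scaling it was 69. The 115 positive and 13 negative calls became 1053 and 713 without HFD-IF library 0.

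The fasting effects on the 2 diets share no library, and across liver genes, which are not independent replicates, they had a Pearson r of 0.367 and a Spearman rho of 0.338. Of the 2756 genes called on chow, 2100 (76.2%) had the same sign on high-fat diet, with a median ratio of 0.311. In both fasting contrasts 29 genes rose and 87 fell, where independent lists share 5.82 and 10.8, and 1 gene was called in opposite directions.

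**Figure D3:**
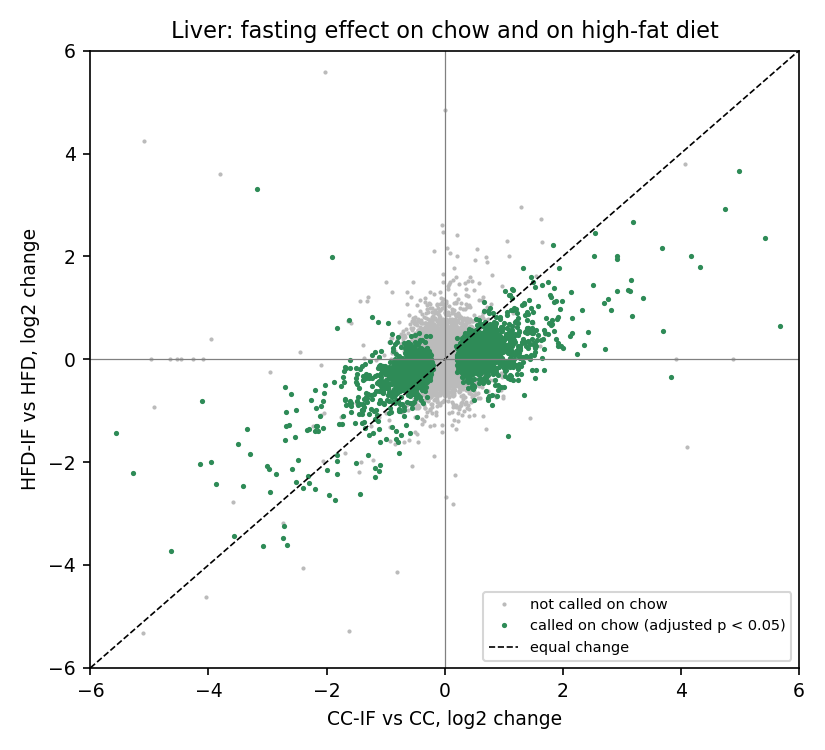
Log2 change with fasting on chow (horizontal axis) against that on high-fat diet (vertical axis) for 11467 liver genes on the log2(FPKM + 1) scale, green where called on chow, with a dashed line of equal change; 30 genes lie outside the axes. Over the 2756 genes called on chow, the median ratio of the change on high-fat diet to that on chow was 0.311.

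Succinate metabolism was examined by 19 measured genes in liver. On chow without fasting 0 rose and 3 fell, 7 adjusted over the list alone: Abat of the GABA shunt (-0.90 ± 0.11), the mitochondrial dicarboxylate carrier Slc25a10 (-0.89 ± 0.20) and Dlst of the oxoglutarate dehydrogenase complex (-0.36 ± 0.07). Slc25a10 lost its call without HFD library 3, 2 or 0 or CC library 0, 2 or 1, at -0.77 to -0.89 (limma adjusted p from 0.0799 to 0.116), and Dlst without the same ones except CC library 2, at -0.34 to -0.36 (0.0565 to 0.0707). Adjusted p was 1.29e-05 in limma's camera, and adjusted p = 0.653 with an estimated correlation. With fasting on chow 9 rose and 1 fell, the same numbers as adjusted over the list alone. Adjusted p was 0.00391 in limma's camera, and adjusted p = 0.513 with an estimated correlation. Those that rose were Slc25a10 (1.33 ± 0.20), Abat (0.76 ± 0.11), Aldh5a1 (0.63 ± 0.11), Suclg1 (0.53 ± 0.08), Sdhd (0.51 ± 0.09), Dlst (0.48 ± 0.07), Suclg2 (0.43 ± 0.09), Ogdh (0.38 ± 0.06) and Sdhc (0.31 ± 0.07). The succinate receptor gene Sucnr1 (chromosome 3, 60081869 to 60087566) fell from 29.1 ± 4.38 to 13.2 ± 4.09 FPKM (-1.11 ± 0.28, limma adjusted p = 0.0121, n = 4 and 4). Against HFD at 39.7 ± 7.41 FPKM, CC-IF was lower by -1.54 ± 0.28 (limma adjusted p = 0.00229). HFD-IF at 17.0 ± 12.4 FPKM and CC did not pass (-1.35 ± 0.34 and -0.43 ± 0.28, limma adjusted p = 0.0754 and 0.445), and CC-IF against HFD-IF was -0.18 ± 0.34. Without HFD-IF libraries 1 and 0, HFD-IF against HFD was -0.59 and -2.12 (limma adjusted p = 0.438 and 0.00113) and CC-IF against HFD-IF was -0.95 and 0.58 (0.252 and 0.208).

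Against HFD, CC-IF livers had 3 higher and 2 lower succinate genes, the same numbers as adjusted over the list alone, namely Ogdh (0.42), Sdhd (0.41), Suclg1 (0.24), Sucnr1 and the dicarboxylate transporter Slc13a3 (-0.74). Suclg1 lost its call without HFD library 2 or 1 or CC-IF library 0, 1 or 3, with log2 changes of 0.24, 0.21, 0.25, 0.20 and 0.24 and limma adjusted p from 0.0635 to 0.0976. Of the succinate dehydrogenase subunits, Sdha and Sdhb did not pass in any liver contrast with all libraries. Their log2 changes were -0.17 and -0.24 for CC against HFD, -0.29 and -0.33 for HFD-IF against HFD, 0.09 and 0.16 for CC-IF against CC, 0.22 and 0.26 for CC-IF against HFD-IF, and -0.08 and -0.08 for CC-IF against HFD. Without HFD-IF library 0, Sdha and Sdhb passed for HFD-IF against HFD at -0.65 and -0.51 (limma adjusted p = 0.00366 and 0.0283), and Sdha and Sdhd for CC-IF against HFD-IF at 0.57 and 0.53 (0.00778 and 0.0248). Sdhc and Sdhd were at -0.26 and -0.10, -0.17 and -0.04, and 0.22 and 0.46 in the contrasts CC against HFD, HFD-IF against HFD and CC-IF against HFD-IF, and Sdhc at 0.05 for CC-IF against HFD.

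In liver no set test passed in any contrast for acute phase, adipocytes, autophagy, bile acid, cholangiocyte, glycolysis, heat shock, ketone body, NRF2 and red blood cell genes (camera in limma, smallest adjusted p from 0.0661 to 0.245). Lymphocyte and pancreas lists had 1 measured gene each.

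In hippocampus the same contrasts gave 0, 0, 1, 0, 0 and 0 called genes in limma, in the order CC against HFD, HFD-IF against HFD, CC-IF against CC, CC-IF against HFD-IF, CC-IF against HFD and the interaction, with 458, 977, 822, 383, 1131 and 436 at an unadjusted p under 0.05. All 11 measured meningeal genes were lower than in HFD in CC, HFD-IF and CC-IF, with 0 past the threshold. In limma's camera with an estimated correlation the list had adjusted p = 0.00399, 0.00722 and 0.053. In 6 of the 15 libraries the ribosomal RNA gene Rn45s was at 18900 to 29300 FPKM, and in the other 9 it was listed at 0; HFD had 2 of the 6, HFD-IF 1, CC 1 and CC-IF 2. Fits on the 9 therefore hold 2, 3, 3 and 1 libraries, and the 1 CC-IF library is assumed to vary like the other groups.

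For CC against HFD, Ptgds, a prostaglandin D synthase abundant in meninges and choroid plexus (chromosome 2, 25466709 to 25470046), was at 220 ± 29.6 against 455 ± 98.4 FPKM (-1.03 ± 0.16, limma adjusted p = 0.125, n = 4 and 4), and every CC library lay below every HFD library. All 11 measured meningeal genes were lower, 0 past the threshold and 7 adjusted over the list alone, with Slc6a20a at -0.69 and Fmod at -0.45. Adjusted p was 1.05e-26 in limma's camera, and adjusted p = 0.00399 with an estimated correlation. The 15 fibroblast and matrix genes, some of which are also on the meningeal list, were lower as a set, 0 called and 4 adjusted over the list alone, with Col1a2 at -0.60. Adjusted p was 5.71e-09 in limma's camera, and adjusted p = 0.0232 with an estimated correlation. Choroid plexus, thalamus and brain endothelium lists were lower, and 26 synaptic genes higher (median 0.0905), with 0 called and 0 adjusted over the list alone. Adjusted p was 1.02e-12, 5.93e-08, 0.0338 and 0.00221 in limma's camera, and adjusted p = 0.435, 0.2, 0.594 and 0.594 with an estimated correlation. Ttr, the main choroid plexus transcript, ranged from 7.48 to 1744 FPKM between hippocampal libraries. The endothelium median of -0.0796 was -0.0168 without HFD library 3 (camera adjusted p = 0.141). Without HFD library 3 or CC library 2 the count was 1 or 3, with Ptgds among them (limma adjusted p = 0.0109 and 0.0444) and Slc6a20a in the latter (0.0444), and with no filter or without genes under 300 nt it was 1.

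For HFD-IF against HFD, the meningeal list was again lower in all 11 members, 10 adjusted over the list alone, with Fmod at -0.55, Ogn at -0.73, Lum at -1.03 and Ptgds at -0.84 (camera in limma, adjusted p = 3.25e-23, and adjusted p = 0.00722 with an estimated correlation), and the matrix list in 13 of 15, 3 adjusted over the list alone (1.12e-09, and adjusted p = 0.019 with an estimated correlation). The genes with the smallest p were Hspb8, a small heat shock protein (-0.64 ± 0.10), Tmem192 (0.51 ± 0.08) and Fmod (limma, adjusted p = 0.137, 0.137 and 0.138). All 13 choroid plexus genes were lower, also adjusted over the list alone. Adjusted p was 1.45e-16 in limma's camera, and adjusted p = 0.325 with an estimated correlation. Ribosomal protein, oxidative phosphorylation, heat shock, cholesterol, unfolded protein, PPAR alpha, microglia, red blood cell, endothelium and autophagy lists were lower and synaptic, glucocorticoid, clock and oligodendrocyte lists higher. Their camera adjusted p-values in limma ran from 1.71e-12 to 0.0447, with 0 called, 1 red blood cell and 1 endothelial gene lower adjusted over the list alone, and adjusted p from 0.364 to 0.699 with an estimated correlation. The ribosomal and oxidative phosphorylation medians of -0.113 and -0.0857 were -0.0012 and -0.0003 without HFD-IF library 2, with calls kept. In the 9 libraries with Rn45s at 0 they were 0.031 and 0.0471. Without HFD library 3 the endothelium median of -0.0429 was 0.01, without HFD-IF library 0 the oligodendrocyte one of 0.176 was 0.0636, and without HFD-IF library 3 the glucocorticoid one of 0.218 was 0.119 (camera adjusted p = 0.118, 0.553 and 0.0767), and 7 of 17 lists lost their call without some library. The count was 3 without HFD library 3, with Tmem192 and Ptgds among them (limma adjusted p = 0.0393 for each), and 2 with no filter.

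For CC-IF against CC, Dbp (chromosome 7, 45705088 to 45710203) rose from 11 ± 0.979 to 19.7 ± 2.06 FPKM (0.78 ± 0.10, limma adjusted p = 0.0156, n = 4 and 3), and all 3 CC-IF libraries lay above all 4 CC libraries. Groups that did not overlap were found in 8.98% of all 12857 genes, where chance gives 5.71%, so this alone does not set Dbp apart. The clock list had 1 of 18 called, 7 higher and 2 lower adjusted over the list alone, with Nr1d1 at 0.49 and Ciart at 0.93. Adjusted p was 4.89e-08 in limma's camera, and adjusted p = 0.417 with an estimated correlation. Unfolded protein genes were lower in 17 of 19, 0 called and 7 adjusted over the list alone, with Calr at -0.47 and Hsp90b1 at -0.50, and heat shock genes in 16 of 17, 0 called and 5 adjusted over the list alone, with Hspa8 at -0.37. Adjusted p was 8.37e-09 and 2.64e-06 in limma's camera, and adjusted p = 0.434 and 0.671 with an estimated correlation. Glucocorticoid and thalamus lists were higher and microglia, PPAR alpha, oligodendrocyte and cholesterol lists lower, with 0 called and 3, 0, 2, 0, 2 and 0 adjusted over the list alone. Adjusted p was 0.000118, 0.00737, 0.00026, 0.0003, 0.0211 and 0.0453 in limma's camera, and adjusted p from 0.434 to 0.901 with an estimated correlation. The thalamus median of 0.288 was 0.112 without CC-IF library 0, and the oligodendrocyte one of -0.103 was 0.0341 and 0.00736 without CC library 3 and CC-IF library 2 (camera adjusted p = 0.584, 0.537 and 0.486). Dbp lost its call without CC library 3, 1 or 0 or CC-IF library 0 or 1, with log2 changes of 0.80, 0.72, 0.80, 0.71 and 0.79 and limma adjusted p of 0.0574, 0.067, 0.0516, 0.212 and 0.0682. In the fit on these groups alone its adjusted p was 0.0792. In the 9 libraries with Rn45s at 0, of which 1 is CC-IF, its log2 change was 0.79 (0.932), the count 6 and the oligodendrocyte median 0.118 against -0.103, so these values rest on that library. The count was 2 to 6 under 8 further settings.

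For CC-IF against HFD-IF, the smallest p-values belonged to Pcsk6, a proprotein convertase (-0.40 ± 0.09), Pddc1 (0.35 ± 0.08) and Idua, a lysosomal enzyme (-0.35 ± 0.08), each with adjusted p = 1 in limma. Ribosomal protein genes (41 of 45), oxidative phosphorylation (57 of 70), clock, glucocorticoid, glycolysis, choroid plexus and immediate early genes were higher as sets and oligodendrocyte, unfolded protein and PPAR alpha genes lower, with 0 called and 0 adjusted over the list alone. Adjusted p ran from 4.04e-08 to 0.0414 in limma's camera, and adjusted p from 0.643 to 0.891 with an estimated correlation. The choroid plexus median of 0.318 turned to -0.138 without CC-IF library 2, and was -0.0382 with a term for the Rn45s split and -0.294 in the 9 libraries with Rn45s at 0. Ribosomal and oxidative phosphorylation medians of 0.105 and 0.0699 were -0.0125 and 0.00831 without HFD-IF library 2, glucocorticoid and immediate early ones of 0.101 and 0.0982 were -0.00666 and -0.00197 without HFD-IF library 0, and the unfolded protein one of -0.162 was -0.0504 without CC-IF library 0 (camera adjusted p from 0.176 to 0.987). Without some library 8 of the 10 lists lost their call. The count was 6 in those 9, where CC-IF is 1 library, and 1 with no filter.

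For CC-IF against HFD, Cirbp, a cold-inducible RNA-binding protein, was at 53.2 ± 4.84 against 27.6 ± 4.14 FPKM (0.93 ± 0.14), Plin4, a lipid droplet coat protein, at 4.46 ± 0.552 against 1.68 ± 0.399 FPKM (1.04 ± 0.16), and Gng5, a G protein subunit, had a log2 change of -0.68 ± 0.11 (limma adjusted p = 0.0717, 0.0717 and 0.0917, n = 3 and 4). The 11 meningeal genes were all lower, 7 adjusted over the list alone, with Ptgds at -0.78 and Ogn at -0.62, and 12 of 15 matrix genes were lower, 5 adjusted over the list alone. Adjusted p was 7.59e-14 and 2.94e-07 in limma's camera, and adjusted p = 0.053 with an estimated correlation in each. Unfolded protein genes were lower in 18 of 19, 5 adjusted over the list alone (Calr -0.46), and clock and glucocorticoid genes higher in 15 of 18 each, 5 and 3 adjusted over the list alone. Adjusted p was 1.26e-09, 1.41e-06 and 8.69e-07 in limma's camera, and adjusted p = 0.257, 0.219 and 0.267 with an estimated correlation. Choroid plexus, PPAR alpha, heat shock, microglia and endothelium lists were lower and synaptic genes higher, with 0 called and 0 adjusted over the list alone. Adjusted p ran from 7.34e-08 to 0.003 in limma's camera, and adjusted p from 0.138 to 0.403 with an estimated correlation. The count was 1 to 4 under 6 other settings, and 6 in the 9 libraries with Rn45s at 0, of which 1 is CC-IF.

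For the hippocampal interaction, the smallest p-values belonged to Mthfd2, a mitochondrial folate enzyme (-0.70 ± 0.14), Airn, a noncoding RNA (-1.17 ± 0.24), and Ptgds (1.09 ± 0.23), with adjusted p = 0.982 in limma for each. The meningeal list was positive in all 11 genes, 5 adjusted over the list alone. It rests on the high HFD libraries of the comparisons with HFD. Adjusted p was 1.12e-19 in limma's camera, and adjusted p = 0.0142 with an estimated correlation. Choroid plexus, ribosomal protein, oxidative phosphorylation, matrix, thalamus, clock and red blood cell lists were positive and oligodendrocytes negative, with 0 called and 0, 0, 0, 3, 0, 1, 1 and 0 adjusted over the list alone. Adjusted p ran from 2.72e-11 to 0.0198 in limma's camera, and adjusted p from 0.159 to 0.808 with an estimated correlation. The oxidative phosphorylation and ribosomal medians of 0.0506 and 0.111 were -0.0206 and -0.00326 without HFD-IF library 2 (camera adjusted p = 0.172 and 0.0764), and the first was -0.0515 in the 9 libraries with Rn45s at 0, where CC-IF is 1 library and the count was 5, and it was 2 with no filter.

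**Figure D4:**
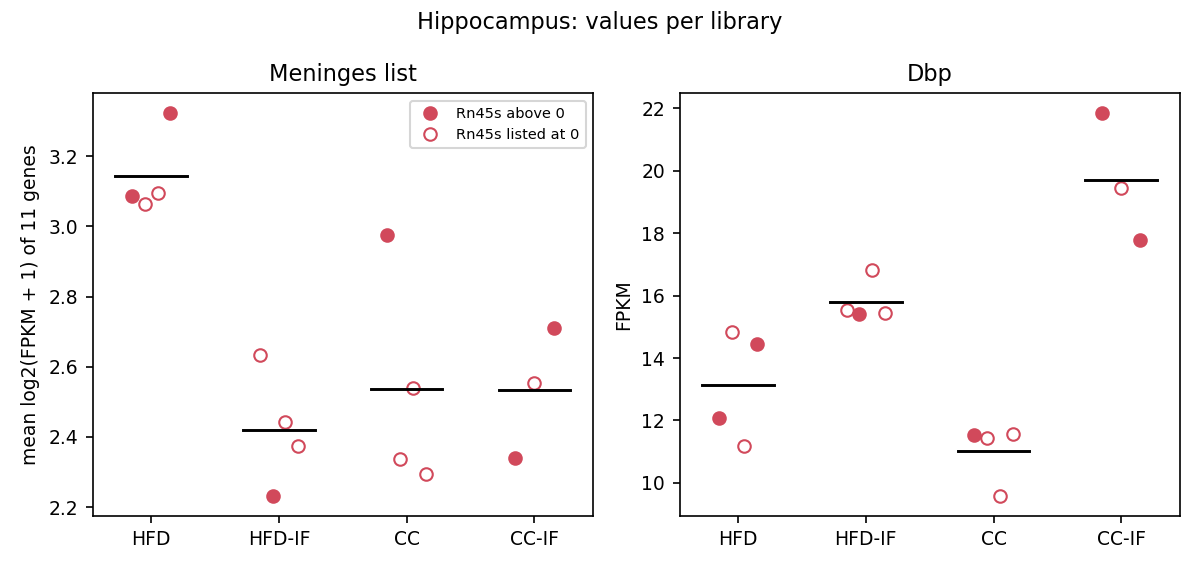
Values per hippocampal library in the 4 regimens, filled where Rn45s was above 0, with a bar at each mean: the mean log2(FPKM + 1) of 11 meningeal genes at left and FPKM of Dbp at right. All HFD libraries lie above the others in the meningeal mean (3.065 or more against 2.976 or less), and all CC-IF libraries lie above the others in Dbp (17.77 FPKM or more against 16.82 FPKM or less).

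The 19 succinate genes measured in hippocampus gave 0 calls in any contrast in limma, and the smallest camera adjusted p of the list was 0.842. Adjusted over the list alone, 1 gene was higher in CC-IF against CC and 1 lower in CC-IF against HFD. The largest log2 change in size among Sdha to Sdhd was -0.20 ± 0.09 for Sdhc in CC-IF against CC. Sdha, Sdhb, Sdhc and Sdhd were at 0.08, 0.08, 0.12 and 0.02 for CC against HFD, 0.08, -0.04, -0.06 and -0.03 for HFD-IF against HFD, and 0.09, 0.12, -0.08 and 0.06 for CC-IF against HFD. They were at 0.01, 0.17, -0.02 and 0.09 for CC-IF against HFD-IF, and Sdha, Sdhb and Sdhd at 0.01, 0.04 and 0.04 for CC-IF against CC. Sucnr1 was under the filter in hippocampus. Neither did a set test pass in any contrast for pyramidal cell (CA1, CA3), granule cell, interneuron, astrocyte, oligodendrocyte precursor, neurogenesis, cortex, striatum, citric acid cycle, fatty acid synthesis, ketone body, mitochondrial biogenesis, ATF4, NRF2, interferon, cell cycle, and insulin, leptin and appetite genes (camera in limma, smallest adjusted p from 0.0614 to 0.58). Lists of MHC class II, adipocytes, and hypothalamus and pituitary had under 3 measured genes.

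Whether the tissues differed was tested on 9939 genes, with all libraries treated as independent, although liver and hippocampal libraries may come from the same mice. For CC against HFD, 138 genes differed in limma, 18 with a higher and 120 with a lower change in liver, for HFD-IF against HFD 162 (47 and 115), and for CC-IF against CC 1367 (874 and 493). The 138 ranged from 63 to 174 without 1 library, and the 162 were 1154 and 64 without liver HFD-IF libraries 0 and 1. Across genes, the fasting effects on the 2 diets in hippocampus had r = 0.0394 and rho = 0.27, with r from -0.0198 without HFD-IF library 3 to 0.148 without HFD-IF library 1.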

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

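Of the tests in this part, the removal of trends on transcript length and GC content and the counts of tissue differences without each library were chosen only after the data had been seen.

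The fasting change in liver differed between the diets for 128 genes by limma's interaction term, with the smallest p for Abhd15 (1.43), Asl (1.45), Rhobtb1 (1.01), Cyp2a5 (3.15), Gpt (1.13) and Arg1 (1.05), each positive and thus more positive on chow. The count of 128 was 49, 48 and 65 without HFD libraries 3, 2 and 0, 1766 and 28 without HFD-IF libraries 0 and 1, 45, 36 and 34 without CC libraries 0, 2 and 1, and 49, 16, 26 and 208 without CC-IF libraries 0, 1, 3 and 2.

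Over the 2756 genes called on chow, the median ratio of the fasting change on high-fat diet to that on chow was 0.311. It was 0.382 without HFD-IF library 1 and 0.238 without library 0, so library 1 alone did not account for it. Genes picked on chow in 2 libraries per group and measured in the other 2 kept a ratio of 0.834 (0.633 to 1.1 over 36 choices), while the same genes on high-fat diet gave 0.328 (0.254 to 0.432), which argues against selection of large effects. With trends on transcript length and GC content removed the ratio was 0.302. A smaller response to fasting on high-fat diet is a candidate explanation, as a hypothesis found and tested on the same data, with only 2 HFD-IF libraries.

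Changes differed between liver and hippocampus for 138 genes in CC against HFD, 162 in HFD-IF against HFD and 1367 in CC-IF against CC, by limma's test of the difference. The 138 became 90, 74 and 78 without liver HFD library 0 and CC libraries 0 and 2, and 65, 68, 63 and 74 without hippocampal HFD library 2 and CC libraries 3, 1 and 0. The 162 became 1154 and 64 without liver HFD-IF libraries 0 and 1, and 90, 96 and 107 without hippocampal HFD libraries 2 and 0 and HFD-IF library 0.

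Single libraries stood far from the other 3 of their group in 25 of 414 groups of 4 tested by Dixon's gap ratio, where chance gives about 1 in 20 groups, or 20.7. In liver HFD, library 1 had Hadh at 216 FPKM (others 269 to 272) and Kynu at 135 (109 to 111). HFD library 2 had Sdhc at 166 (179 to 181) and Ppp1r3b at 94.3 (146 to 157), and HFD library 3 had Cyp2a4 at 2.17 (0 to 0.115). In liver CC, library 3 had Acaa1a at 80.4 (49 to 52.6), Calr at 624 (780 to 812), Atf4 at 43 (58.9 to 60.7) and Snora47 at 455000 (340000 to 350000), and library 1 had Rhobtb1 at 28.1 (24.6 to 25). In liver CC-IF, library 1 had Cfd at 0.521 (others listed at 0) and Acaa1a at 173 (150 to 153), and library 0 had Ifit1 at 2.87 (1.68 to 1.76). Library 3 had Snora30 at 464000, and library 2 had Snora47 at 148000 and Snora75 at 89300, each with the others listed at 0.

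In hippocampal HFD, library 1 had Sdhb at 47.7 FPKM (others 44.7 to 45.1) and Mthfd2 at 1.81 (2.21 to 2.27), and library 2 had Airn at 0.324 (0.538 to 0.544). In hippocampal HFD-IF, library 2 had Slc6a20a at 2.79 (3.87 to 4.01), Sdhb at 36.8 (46.5 to 47.4) and Rbm3 at 31.9 (57.8 to 62.8), and library 0 had Dbp at 16.8 (15.4 to 15.5) and Gng5 at 14.9 (18.6 to 19.1). In hippocampal CC, library 1 had Dbp at 9.57 (11.4 to 11.6).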

How the results depend on the processing

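Leaving out genes under 300 nt, removing length and GC trends, the Rn45s split as a term, the 9 libraries with Rn45s at 0, leaving HFD-IF library 1 out of the shared spread, the column index as a replicate block, and leaving out libraries for lists, correlations and tissue differences were chosen only after the data had been seen. Planned fits with the replicate number of the labels as a block were not run, since columns count from 0, labels from 1, and columns were tied to groups only. The column index served in its place, although it did not pair libraries. Deviations of libraries with the same index correlated by over 0.1 in 3 of 18 pairs in liver, 8 of 21 in hippocampus and 0 of 13 between the tissues, and 7 of 14, 5 of 15 and 5 of 26 libraries correlated best with their own index. With the index as a replicate block, counts were 125, 107, 2515, 4, 2456 and 22 in liver and 0, 2, 4, 0, 4 and 0 in hippocampus (CC against HFD, HFD-IF against HFD, CC-IF against CC, CC-IF against HFD-IF, CC-IF against HFD, interaction) and 173, 188 and 1490 for tissue differences in the first 3. Values of named genes kept their sign and side of the threshold in 218 of 223 with a pseudocount of 0.1, 202 of 223 with no filter, 213 of 222 with median-ratio scaling, 178 of 214 in fits on the 2 groups compared and 186 of 223 with the index block, and no called value changed sign there. No list call of 90 in liver (0) and 5 of 62 in hippocampus held with an estimated correlation. The cause was not tested for the changes given here, except that fits on fewer groups or libraries rest on fewer samples. Liver CC against HFD (265) gave 512 with HFD-IF library 1 out of the spread and 497 in the fit on 2 groups. HFD-IF against HFD (152) gave 8 in the fit on 2 groups, CC-IF against HFD-IF (68) gave 3 there and 30 with no filter, and the interaction (128) gave 69 with median-ratio scaling. The 9 libraries hold 1 CC-IF library, assumed to vary like the other groups, so their CC-IF and interaction values rest on it. In hippocampus, CC against HFD (0) gave 1 with no filter and 1 without genes under 300 nt, and HFD-IF against HFD (0) gave 2 with no filter. CC-IF against CC (1) gave 2 with a pseudocount of 0.1, 3 with no filter, 2 with median-ratio scaling, 3 without genes under 300 nt, 6 with trends removed, 2 with the Rn45s split as a term, 6 in the 9 libraries and 2 in the fit on 2 groups. CC-IF against HFD-IF (0) gave 1 with no filter and 6 in the 9 libraries. CC-IF against HFD (0) gave 1 with no filter, 2 with median-ratio scaling, 3 without genes under 300 nt, 4 with the split as a term, 6 in the 9 libraries and 1 in the fit on 2 groups, and the interaction (0) gave 2 with no filter and 5 in the 9 libraries. In the 9 libraries, medians became 0.0471 (oxidative phosphorylation) and 0.031 (ribosomal proteins) for HFD-IF against HFD, 0.118 (oligodendrocytes) for CC-IF against CC, -0.294 (choroid plexus) and 0.00306 (glycolysis, where the set test turned) for CC-IF against HFD-IF and -0.0515 (oxidative phosphorylation) for the interaction. With the split as a term, CC-IF against HFD-IF gave -0.0382 (choroid plexus) and 0.0687 (immediate early genes, where the set test turned). Where an HFD-IF liver was left out, the other was assumed to vary like the other groups. Without 1 library, liver counts ranged from 51 (HFD library 0) to 245 (HFD library 1) for CC against HFD, 5 to 1633 (HFD-IF libraries 1 and 0) for HFD-IF against HFD, 1 (CC-IF library 0, 1 or 3) to 1773 (HFD-IF library 0) for CC-IF against HFD-IF, and 16 (CC-IF library 1) to 1766 (HFD-IF library 0) for the interaction. The libraries that moved each count are named with the results. Hippocampal counts ranged from 0 to 3 for CC against HFD (1 without HFD library 3, 3 without CC library 2), 0 to 3 for HFD-IF against HFD (3 without HFD library 3) and 0 to 1 for CC-IF against CC. Tissue differences ranged from 63 (hippocampal CC library 1) to 174 (liver HFD library 1) for CC against HFD and 64 to 1154 (liver HFD-IF libraries 1 and 0) for HFD-IF against HFD. Liver list medians without HFD-IF libraries 1 and 0 were 0.0441 and 2.36 (macrophages), -0.3 and 1.85 (MHC class II), -0.00973 and 1.24 (matrix) and -0.0951 and 1.29 (interferon) for HFD-IF against HFD, and 0.125 and -1.54 (Kupffer cells), 0.753 and -2.13 (macrophages), 0.242 and -2 (MHC class II) and 0.14 and -1.25 (matrix) for CC-IF against HFD-IF. For the interaction they were 0.639 and -2.27 (macrophages) and -1.42 and 0.435 (male-biased). The hippocampal choroid plexus median in CC-IF against HFD-IF ranged from -0.138 (without CC-IF library 2) to 0.593 (without CC-IF library 0). List medians whose call held moved by over 1.5 times without 1 library in 43 cases in liver and 89 in hippocampus. Depth was only estimated, so no limit of detection is given.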

Other observations

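The comparison of the Rn45s sets with the regimens, the test of Rn45s reads by scaling alone, both tests of the meningeal genes, the reading of the split with 86 genes by Ttr, the bound on the spread for length and GC content, and the naming of Cirbp and Rbm3 in CC-IF against CC were chosen only after the results had been seen.

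Cirbp and Rbm3 encode RNA-binding proteins that are known to respond to mild cooling. In hippocampus Cirbp was at 53.2 ± 4.84 FPKM in CC-IF and 27.2 ± 1.10 FPKM in CC (0.94 ± 0.14), and Rbm3 had a log2 change of 1.10 ± 0.20 (limma adjusted p = 0.059 and 0.109, n = 3 and 4). In liver Rbm3 rose by 1.34 (limma adjusted p = 0.000109) and Cirbp had a log2 change of 0.52 (limma adjusted p = 0.118), so a body-wide response, which needs both genes to pass in liver, was left undecided by the lower value, 0.522.

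With fasting on chow, 11 of 18 clock genes rose in liver and 3 fell in limma, among the latter Arntl and Npas2 by 2.05 and 1.72 (camera, adjusted p = 0.247 with an estimated correlation). Tef and Hlf, output factors related to Dbp, rose by 2.83 and 1.51, and Cry2 by 1.28, while 4 did not pass, among them Cry1 and Nr1d1 with changes of 0.03 and 0.46. Whether direction followed the phase of a gene was not tested. Over 17 clock genes, which are not independent replicates, liver and hippocampal changes had a Spearman rho of 0.483 and a Pearson r of 0.581 (one-sided permutation p = 0.0258 for rho, 100000 resamples), with 16 of the same sign, which is consistent with a shared shift of the clock as a hypothesis.

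Rn45s was at 18900 to 29300 FPKM in 6 hippocampal libraries and listed at 0 in the other 9, and 4246 genes differed between these sets in limma, 330 higher and 3916 lower in the 6, or 1217 and 1199 with median-ratio scaling, which centres each library. All 4 regimens have libraries in both sets, so the regimens do not account for the split. Of the 4246, 36% were still called with median-ratio scaling alone (29.7% to 38% without each library) and 51.2% with length and GC trends removed (29.4% to 51.5%), which argues against a common factor per library or these trends as the whole cause, while as a part of it length and GC bias cannot be told apart from other causes. Over the 6 libraries the scaling factor fell as Rn45s rose (r = -0.934, rho = -0.886, one-sided exact permutation p = 0.0167 for each). The 2 lowest in Rn45s were CC-IF, so regimen is not ruled out (r = -0.597 without them). Rn45s reads taking a share of the 6 may be a part. The size of that share was not tested, scaling removes a common factor of any origin, and no biological explanation was tested.

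The mean log2(FPKM + 1) of 11 meningeal genes was lower in every library of the other regimens than in every HFD library. The 3 comparisons share the 4 HFD libraries, and each had two-sided exact permutation p = 0.0286, the smallest their splits can give. Adjusted p was 0.0856 over 9 comparisons of 3 lists. The Rn45s sets did not account for the lower mean, since with the set as a term at least 98.1% of the median change was left. Between libraries of the same group the members varied together, with a mean pairwise correlation of 0.286 against a 95th percentile of 0.217 over 1000 random lists, which is consistent with varying amounts of meninges in the dissected pieces. The regimens stay open, untested. Exact permutation p was 0.314, 0.0571 and 0.171 for 13 choroid plexus genes and 0.0857, 0.0571 and 0.0571 for 12 of the matrix genes.

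Other splits of the libraries were counted for each contrast with at least 3 libraries per group. Liver counts were 265 in CC against HFD, 2756 in CC-IF against CC and 2726 in CC-IF against HFD. Of 35 splits only the real one gave as many, the fewest possible (highest others 10, 1 and 1), which argues against chance. For the 1 gene of hippocampal CC-IF against CC, Dbp, 1 of 35 splits gave as many and the highest other count was 0, but 1 against 0 decides little. Dbp lost its call in the fits named with its result, where its log2 change stayed between 0.71 and 0.80. The hippocampal counts of 0 say nothing of chance, because any split gives at least 0. The highest other counts there were 86 in CC against HFD, 2 in HFD-IF against HFD, 1 in CC-IF against HFD-IF, 0 in CC-IF against HFD and 2 for the interaction. The split with 86 genes put on 1 side the 4 libraries with Ttr at 1246 to 1744 FPKM. The others had 14.2 to 74.1 FPKM. Of the 4, 3 had Rn45s above 0 (not HFD library 3), against 0 of the others. Whether the split goes with Ttr or Rn45s cannot be told. For tissue differences, 1 of 100 assignments gave as many as 138 in CC against HFD and 1367 in CC-IF against CC. The highest others, 54 and 1362, kept or swapped the liver groups, and the rest gave at most 13 and 2. Liver changes alone can raise such counts, so this test cannot decide.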
